A study of Mus musculus with 9 samples.

How the data were processed

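Whole-kidney RNA from mice of the 129X1/SvJ strain was profiled in 9 libraries at 9 weeks of age, per the labels. The libraries formed 3 groups of 3: wild type (WT, no treatment per the labels), Col4a3 knockout given PBS (KO_PBS), and Col4a3 knockout given an inhibitor of the microRNA miR-21 (KO_antimiR21). Loss of Col4a3, which encodes the alpha-3 chain of type IV collagen in the glomerular basement membrane, is used as a mouse model of Alport syndrome. Groups and replicate numbers were taken from the sample titles and descriptions. Labels do not say whether the libraries of a group came from separate animals, so p-values measure only the spread between these samples. RNA was extracted with a miREASY kit and libraries were made from 150 ng of total RNA with the TruSeq RNA v2 kit, per the labels' protocols. Strand was not given in the sources used here, so overlapping and antisense genes were not separated.

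Each library had a deposited table of expected counts per gene symbol (22637 symbols), made with Bowtie and RSEM against the mm9 mouse genome, per the submitters' processing notes. Versions and gene annotation were not given in the sources used here. Between 9848 and 10931 of the expected counts per deposited table were not whole numbers, and 111 symbols were at 0 in every library. The tables held 97 symbols that differed from another only in letter case, and these were kept apart. RSEM shares reads among near-identical copies, so single members of multigene families such as the globins are uncertain. The authors also deposited a log2 matrix of the 9 libraries, and limma is named in the submitters' processing notes. Each of its columns equalled log2 CPM, with 0.5 added to the count and 1 to the library size, plus 1 constant per library, to within 5.1e-14. Total expected counts were 26448275 to 31786624 per library. Replicates were not copies of one another: the chi-square per gene between pairs of the same group was 31.1 to 139.7.

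Expected counts were rounded to whole numbers, and genes were kept by the filterByExpr rule of edgeR, which left 17315 genes. All 9 libraries entered 1 fit with 3 group means, TMM normalization and the edgeR quasi-likelihood F test. TMM factors ran from 0.894 (WT 1) to 1.15 (KO_PBS 1). The p-values were two-sided and adjusted by Benjamini-Hochberg within each of the 3 comparisons, and a gene passed at an adjusted p under 0.05. Every adjusted p given for a gene is from this edgeR test unless another tool is named. CPM values (counts relative to the TMM-scaled library total) are given as mean ± SD with n = 3 per group, and log2 fold changes as estimate ± SE. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

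Before the data were examined, the groups, tests, alternatives, the rule for named genes and 38 gene lists were fixed. Of the lists, 34 had at least 5 tested genes and were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera asks whether a list's genes rank apart from other genes. It was run again with the correlation estimated from these libraries. Fry, a rotation test of whether a list's genes moved one way on balance, was run beside it. Some symbols in the tables are older than those of the lists, and older names were matched by hand (for example Cdc2a for Cdk1 and Adfp for Plin2).

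The named-gene rule took Col4a3, Col4a4 and Col4a5, then the 8 higher and 8 lower genes with the largest change among those past the threshold with a mean log2 CPM of at least 2 and no overlap between the groups. Where fewer than 3 genes passed, it took the 10 genes with the lowest p. It also took the 3 members of each list with the lowest p. The text gives part of these, and the part was chosen after the alternatives had been run. Some genes that the rule takes are not reported here.

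Sex was called from the Y-linked Ddx3y, Eif2s3y, Jarid1d (Kdm5d) and Uty, with a sum of at least 10 CPM counted as male. The plan had also named Xist, a symbol not found in the tables used here. Their summed CPM was 0.83 in WT 1 and 1.4 in WT 3, and 105.68 in WT 2. In the knockout libraries it ran from 100.71 to 120.21. Sex letters in the deposited names of the WT libraries match these calls. A library code in the deposited names, whose meaning was not given in the sources used here, was L4 for the 3 WT libraries and KO_PBS 1 and 2, and L5 for KO_PBS 3 and the 3 KO_antimiR21 libraries.

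Sites for the miR-21 seed (the part of a microRNA that pairs with its targets) were searched in the longest annotated 3' untranslated region of each symbol, from GENCODE vM21 on GRCm38. That build differs from the one named for the counts, so only sequences were used and no coordinates are given. A region was found for 14171 of the 17315 tested genes (81.8%), and the others were not searched. The 8-mer site was ATAAGCTA and the 7-mer-m8 site ATAAGCT. Controls for the 8-mer were 100 shuffles of its bases. Controls for the 7-mer-m8 site were the 7-mers that begin these shuffles, which need not have its base composition.

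Each tool was tested on simulated counts with 200 genes changed by known folds. In the KO_PBS against WT simulation (17130 genes), edgeR recovered 85.7% of 4-fold, 22% of 2-fold and 2.6% of 1.5-fold changes. For KO_antimiR21 against KO_PBS (17097 genes) the shares were 88.6%, 11.5% and 0%, and for KO_antimiR21 against WT (17092 genes) 89.3%, 24.6% and 0%. In the KO_antimiR21 against KO_PBS simulation DESeq2 made 166 calls, 51 of them false, where edgeR made 71 with 2 false. A single list, the TCA cycle, raised by 1.5-fold was found by camera in each of the 3 simulations with 0 of the other lists called. Genes were drawn independently there, so the preset correlation of 0.01 held by construction. In the real libraries the estimated correlation of that list was 0.839 in KO_PBS against WT. False list calls at such correlations were not tested.

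Alternatives were other normalizations (RLE, upper quartile, library size only), other low-count filters, DESeq2, limma-voom, limma on the deposited log2 matrix, a robust edgeR fit, expected counts left unrounded, only the compared groups in the fit, the replicate number as a block, sex or library code as a covariate, stricter thresholds, and each library left out in turn. A fit on male libraries only was added after seeing the data. Comparisons that share libraries were set beside 20 simulations of unchanged groups that share them, with each gene drawn independently.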

Results

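Messenger RNA of the whole kidney was counted in 9 libraries: 3 from wild-type mice (WT), 3 from Col4a3 knockout mice given PBS (KO_PBS) and 3 from Col4a3 knockout mice given a miR-21 inhibitor (KO_antimiR21), all at 9 weeks of age. Total expected counts ran from 26448275 (KO_antimiR21 1) to 31786624 (KO_PBS 1), so the groups were of similar depth. The 20 most abundant genes of each library took 21.1% to 22.1% of the counts in WT and 14.1% to 16.2% in KO_PBS, against 21.4%, 15.6% and 20.9% in KO_antimiR21 1, 2 and 3. By Y-linked transcripts WT 1 and WT 3 were female and the other 7 libraries male, so sex differed between WT and both knockout groups. Wild-type mice had no injection per the labels, so genotype was compared together with the injection.

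The targeted gene was measured first. Col4a3 stood at 371, 257 and 316 CPM in WT 1, 2 and 3. In KO_PBS 1, 2 and 3 it stood at 44.3, 94.3 and 60.2 CPM, and in KO_antimiR21 1, 2 and 3 at 104, 70.6 and 138 CPM. Every knockout library was below every WT library. Against WT, Col4a3 fell in KO_PBS (log2 fold change -2.25 ± 0.33, edgeR adjusted p = 0.0025) and in KO_antimiR21 (-1.59 ± 0.32, edgeR adjusted p = 0.0191). Counts covered the whole transcript, so reads outside a deleted part remain in such a measure. The call in KO_antimiR21 was lost when WT 1, WT 3, KO_antimiR21 1 or KO_antimiR21 2 was left out (edgeR adjusted p = 0.0637, 0.0608, 0.0732 and 0.0753). Over all alternatives it ran from 5.48e-05 to 0.42. With sex as a covariate the value in KO_PBS was -1.96 (edgeR adjusted p = 0.0555), and among male libraries -1.93 (edgeR adjusted p = 0.0736). Over all 17 fits other than the main one its sign was negative. Its partner chains of the glomerular basement membrane were not past the threshold in KO_PBS: Col4a4 was at -0.54 ± 0.32 (edgeR adjusted p = 0.259) and Col4a5 at -0.26 ± 0.23 (edgeR adjusted p = 0.466). Without KO_PBS 1 these stood at -0.27 and -0.05, and without KO_PBS 3 Col4a4 stood at -0.82 and Col4a5 at -0.45.

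The first comparison asked what differed between the kidneys of PBS-injected knockout mice and those of wild-type mice. By camera, lists of interstitial matrix, chemokine, tubular injury and cell cycle genes rose in KO_PBS and lists of tubule segment markers, oxidative phosphorylation and branched-chain amino acid breakdown fell, among 25 of 34 lists called, where 0 were called with an estimated correlation and 23 by fry. Among the named genes with the largest rises were Timp1, an inhibitor of matrix-degrading enzymes, from 1.67 ± 1.68 to 106 ± 77.4 CPM (log2 fold change 5.99 ± 0.84, edgeR adjusted p = 0.0021), and Ltbp2, an extracellular matrix glycoprotein (5.21 ± 0.70, edgeR adjusted p = 0.00194). Il1rn, the antagonist of the interleukin-1 receptor, rose by 5.05 ± 0.67, and Ccl2, a chemokine that draws monocytes, by 4.45 ± 0.77. Among the named genes with the largest falls were Bhmt, a betaine-dependent methyltransferase, from 102 ± 84.7 to 1.99 ± 1.29 CPM (-5.69 ± 1.14, edgeR adjusted p = 0.00873), and Slc22a7, an organic anion transporter (-5.55 ± 0.89, edgeR adjusted p = 0.00351).

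In all, edgeR called 4226 of the 17315 genes, 2521 higher and 1705 lower in KO_PBS, and 2814 of them changed by at least 1 on the log2 scale. Lower genes numbered 667, 773, 973 and 978 without KO_PBS 1, KO_PBS 2, WT 1 and WT 3, and higher genes 1756, 1811, 1960 and 1855. Of the fits with 1 library left out, that without KO_antimiR21 2 had the most lower genes, 1855. The groups did not overlap for 7457 genes (43.1%), where chance gives 10%. With library size as the only scaling, the split was 3753 higher and 904 lower, and the median log2 fold change of all genes was 0.25, against -0.03 with TMM. Other named rises were Krt20, a keratin (5.0 ± 1.0), Serpina3n, a serine protease inhibitor (4.63 ± 0.73), Ubd, a ubiquitin-like modifier (4.61 ± 0.88) and Mybpc2, a myosin-binding protein (4.45 ± 0.55), with edgeR adjusted p from 0.00157 to 0.00871. Krt20 was at 7.81 without WT 2. Other named falls were Pvalb, a calcium-binding protein of the distal convoluted tubule (-4.35 ± 0.65), Hpd, an enzyme of tyrosine breakdown (-4.30 ± 0.93), Dnase1 (-4.07 ± 0.90), Slc22a9 (-3.95 ± 0.71), Egf, a growth factor made in the distal nephron (-3.76 ± 0.87), and Aadat, an aminotransferase (-3.56 ± 0.81), with edgeR adjusted p from 0.0026 to 0.0158.

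The matrix and growth factor lists rose. Of 32 genes of interstitial extracellular matrix, 29 rose (31 adjusted over the list alone), with a median log2 fold change of 2.47 (camera adjusted p = 7.33e-33, and adjusted p = 0.0875 with an estimated correlation). Col12a1, a fibril-associated collagen, went from 11.2 ± 1.33 to 66.8 ± 3.78 CPM (2.57 ± 0.20), Col5a2, a fibrillar collagen chain, rose by 2.91 ± 0.24, and Mmp2, a gelatinase, by 2.51 ± 0.24. Among 14 genes of the TGF-beta response 10 rose, and also 10 adjusted over the list alone, with Tgfbi at 3.04 ± 0.32 and Ctgf, a matricellular growth factor, at 2.30 ± 0.32. The median was 1.49 (camera adjusted p = 1.36e-08, and adjusted p = 0.0875 with an estimated correlation). In the list of PDGF and wound growth factors, 5 of 10 genes rose and 2 fell (6 and 2 adjusted over the list alone), with Pdgfb at 2.22 ± 0.19 and Csf1, the growth factor of macrophages, at 2.49 ± 0.27. Its median was 1.02 (camera adjusted p = 0.00477, and adjusted p = 0.0875 with an estimated correlation). Of 11 myofibroblast and pericyte markers 6 rose, also 6 adjusted over the list alone, among them Tagln (2.66 ± 0.30), Vim (2.26 ± 0.32) and Thy1 (3.26 ± 0.45). Their median was 1.14 (camera adjusted p = 2.29e-06, and adjusted p = 0.158 with an estimated correlation). The 6 type IV collagen chains parted: Col4a1 and Col4a2, the chains of ordinary basement membranes, rose by 1.96 ± 0.25 and 1.91 ± 0.25, while Col4a3 fell. These counts were the same adjusted over the list alone. The median of the chains was -0.08, the mean 0.15 and the camera direction upward (adjusted p = 0.574, and adjusted p = 0.706 with an estimated correlation). That median ran from -0.33 without WT 1 to 0.29 without WT 2, and was also above 0 without KO_PBS 1.

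Injury and proliferation genes rose as well. Of 18 tubular injury genes 16 rose (17 adjusted over the list alone), with a median of 2.72 (camera adjusted p = 1.67e-15, and adjusted p = 0.0875 with an estimated correlation). Spp1, which encodes osteopontin, went from 1606 ± 376 to 20230 ± 5645 CPM (3.65 ± 0.45), and Tnfrsf12a, the TWEAK receptor, rose by 2.74 ± 0.34. All 23 cell cycle genes rose, also 23 adjusted over the list alone, with a median of 2.40 (camera adjusted p = 7.82e-33, and adjusted p = 0.0875 with an estimated correlation). Examples were Mcm3, a replication licensing factor (1.97 ± 0.17), Ccna2, a cyclin (2.38 ± 0.21), and Cdc2a, the kinase now named Cdk1 (3.30 ± 0.30). Of 12 genes of ER stress and amino acid response 3 rose, including Trib3 at 1.83 ± 0.36 (3 rose and 1 fell adjusted over the list alone). Their median was 0.18 (camera adjusted p = 0.364, and adjusted p = 0.665 with an estimated correlation) and turned below 0 without KO_PBS 3. Immediate early genes were listed as a check of sample quality, not of injury. Relative to the WT mean, their mean log2 CPM was -1.63, 0.81 and 0.82 in WT 1, 2 and 3. Of these 12 genes 4 rose, Junb by 2.02 ± 0.39 and Jun by 1.38 ± 0.30 among them (4 rose and 1 fell adjusted over the list alone). Their median was 1.06 (camera adjusted p = 0.106, and adjusted p = 0.665 with an estimated correlation). That list passed without WT 2, WT 3 or KO_PBS 3 (adjusted p = 0.0338, 0.0185 and 0.0152), within a range of 0.0152 to 0.854 over all its alternatives. Its median ran from 0.53 without WT 1 (adjusted p = 0.486) to 1.42 without WT 3.

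Immune lists rose. Among 20 genes of chemokines and the NF-kappaB response 18 rose (20 adjusted over the list alone), with Icam1, an adhesion molecule for leukocytes, at 2.74 ± 0.28 and the chemokine Cxcl16 at 1.94 ± 0.25. The median was 3.17 (camera adjusted p = 1.08e-20, and adjusted p = 0.0875 with an estimated correlation). Of 18 interferon response genes 13 rose and 1 fell (15 and 1 adjusted over the list alone), with the GTPases Gbp2 and Irgm at 2.46 ± 0.32 and 1.46 ± 0.19. Their median was 1.36 (camera adjusted p = 4.41e-09, and adjusted p = 0.176 with an estimated correlation). Of 12 complement genes 10 rose (11 adjusted over the list alone), with C1r at 1.89 ± 0.21, C1s at 1.99 ± 0.22 and the C3a receptor gene C3ar1 at 3.06 ± 0.36. Their median was 1.94 (camera adjusted p = 1.2e-12, and adjusted p = 0.0875 with an estimated correlation).

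Markers of infiltrating cells rose alongside these immune lists. Of 16 macrophage markers 15 rose, also 15 adjusted over the list alone, with a median of 3.54 (camera adjusted p = 2.67e-27, and adjusted p = 0.0875 with an estimated correlation). Cx3cr1, a chemokine receptor of monocytes and macrophages, went from 3.37 ± 0.36 to 39.5 ± 2.94 CPM (3.55 ± 0.32), and the complement genes C1qb and C1qc rose by 3.58 ± 0.37 and 3.65 ± 0.38. All 14 T cell markers rose, also 14 adjusted over the list alone, with a median of 2.37 (camera adjusted p = 2.07e-08, and adjusted p = 0.176 with an estimated correlation). Levels were low, as for Zap70 (0.38 ± 0.22 to 2.03 ± 0.38 CPM) and Cd3g (0.31 ± 0.12 to 2.49 ± 0.65 CPM), which rose by 2.39 ± 0.43 and 2.98 ± 0.47. Among 5 neutrophil markers 2 rose, also 2 adjusted over the list alone, with Csf3r at 2.65 ± 0.34. Their median was 1.71 (camera adjusted p = 0.0364, and adjusted p = 0.224 with an estimated correlation). Of 8 B and plasma cell markers 3 rose, also 3 adjusted over the list alone, with a median of 1.05 (camera adjusted p = 0.0497, and adjusted p = 0.41 with an estimated correlation). This list lost its call without WT 1, KO_PBS 1, KO_PBS 2 or any 1 of the 3 KO_antimiR21 libraries (adjusted p = 0.0502 to 0.124), and its median was 1.59 without WT 2. Its alternatives ran from 0.00763 to 0.41.

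Lists of mitochondrial and peroxisomal metabolism fell. Of 73 oxidative phosphorylation genes 64 fell (72 adjusted over the list alone), with the complex I subunits Ndufb5 and Ndufv1 at -1.02 ± 0.19 and -0.94 ± 0.18. The median was -0.95 (camera adjusted p = 3.99e-23, and adjusted p = 0.251 with an estimated correlation). Of 19 TCA cycle genes 16 fell (17 adjusted over the list alone), with Pdhb at -0.98 ± 0.17 and Fh1, fumarate hydratase, at -1.01 ± 0.20. Their median was -0.87 (camera adjusted p = 9.81e-09, and adjusted p = 0.284 with an estimated correlation). Of 21 genes of mitochondrial fatty acid oxidation 12 fell (19 adjusted over the list alone), among them the thiolase gene Acaa2 at -1.51 ± 0.34. Their median was -0.79 (camera adjusted p = 1.56e-07, and adjusted p = 0.273 with an estimated correlation). Of 20 peroxisomal lipid genes 9 fell (13 adjusted over the list alone), with Cat, catalase, at -1.57 ± 0.35. Their median was -0.89 (camera adjusted p = 2.29e-06, and adjusted p = 0.258 with an estimated correlation). Of 17 genes of branched-chain amino acid breakdown 15 fell (16 adjusted over the list alone), including Mccc2 at -1.78 ± 0.28 and Bcat2 at -1.52 ± 0.27. Their median was -1.19 (camera adjusted p = 6.61e-10, and adjusted p = 0.224 with an estimated correlation).

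Smaller metabolic lists were mixed. Among 22 PPAR-alpha targets 2 rose and 5 fell (2 and 7 adjusted over the list alone), with the lipid droplet gene Adfp, now Plin2, at 1.75 ± 0.30 and Fabp3 at -1.06 ± 0.21. Their median was -0.49 (camera adjusted p = 0.0838, and adjusted p = 0.522 with an estimated correlation). The list passed without WT 2 or KO_PBS 3 (adjusted p = 0.00366 and 0.0204), within a range of 0.00366 to 0.522 over its alternatives, and its median ran from -0.25 without KO_PBS 1 to -0.92 without KO_PBS 3. Of 17 antioxidant and NRF2 response genes 2 rose and 6 fell (2 and 7 adjusted over the list alone), with heme oxygenase Hmox1 at 1.78 ± 0.27 and the superoxide dismutases Sod1 and Sod2 at -1.36 ± 0.27 and -1.18 ± 0.24. Their median was -0.58 (camera adjusted p = 0.0364, and adjusted p = 0.364 with an estimated correlation), and the call was lost without WT 2 (-0.38, adjusted p = 0.095) or KO_PBS 1 (-0.49, adjusted p = 0.0622), within a range of 0.00358 to 0.364. Of 15 cholesterol synthesis genes 5 fell (7 adjusted over the list alone), with Cyp51 at -2.64 ± 0.51. Their median was -0.49 (camera adjusted p = 0.00118, and adjusted p = 0.342 with an estimated correlation). Of 7 renin-angiotensin genes 1 fell, Ren1, which encodes renin, by 2.19 on the log2 scale, also 1 adjusted over the list alone. The median was -0.71 (camera adjusted p = 0.0388, and adjusted p = 0.393 with an estimated correlation). That call was lost without WT 1 (-0.42), KO_PBS 1, KO_antimiR21 2 or KO_antimiR21 3 (adjusted p = 0.0587 to 0.117), within a range of 0.00848 to 0.393.

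Markers of tubule segments fell beside these metabolic lists. Of 25 proximal tubule markers 11 fell and 1 rose (12 and 1 adjusted over the list alone), with Miox, the enzyme that breaks down inositol, from 1822 ± 551 to 240 ± 128 CPM (-2.92 ± 0.60) and the water channel Aqp1 at -1.49 ± 0.34. Their median was -1.29 (camera adjusted p = 1.96e-06, and adjusted p = 0.342 with an estimated correlation). Of 12 markers of the thick ascending limb and distal convoluted tubule 7 fell, also 7 adjusted over the list alone, with the sodium-potassium-chloride cotransporter Slc12a1 from 1642 ± 370 to 483 ± 149 CPM (-1.76 ± 0.32) and the potassium channel Kcnj1 at -1.36 ± 0.23. Their median was -1.36, and -0.89 without WT 1 (camera adjusted p = 3.23e-05 with all libraries, and adjusted p = 0.158 with an estimated correlation). Of 13 collecting duct markers 7 fell (8 adjusted over the list alone), with the anion exchanger Slc4a1 at -2.61 ± 0.47. Their median was -0.95 (camera adjusted p = 3.54e-05, and adjusted p = 0.0929 with an estimated correlation). Of 15 podocyte markers 4 rose, also 4 adjusted over the list alone. Their median was 0.52 (camera adjusted p = 0.112, and adjusted p = 0.527 with an estimated correlation). That list passed without WT 1 or KO_PBS 1 (adjusted p = 0.0302 and 0.0439), within a range of 0.000155 to 0.527, and its median was 0.26 without WT 2 (adjusted p = 0.438). Of 17 endothelial markers 1 fell, the angiopoietin receptor gene Tek (-0.57 ± 0.17), but 0 in the edgeR test adjusted over the list alone. Tek lost its call without WT 1, WT 3, KO_PBS 1, KO_PBS 3, KO_antimiR21 1 or KO_antimiR21 3 (edgeR adjusted p = 0.0531 to 0.13, and 0.0204 to 0.541 over all its alternatives). The endothelial median was -0.34 (camera adjusted p = 0.0381, and adjusted p = 0.42 with an estimated correlation). Its call was lost without WT 3, KO_PBS 1, KO_PBS 3 or KO_antimiR21 2 (adjusted p = 0.0509 to 0.112), within a range of 0.00743 to 0.42.

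Other cell types and sex-linked genes were followed in the same way. Red blood cell transcripts fell: the hemoglobin chains Hba-a2 and Hbb-b1 went from 52.8 ± 32.7 and 48.9 ± 25.3 CPM in WT to 4.97 ± 2.90 and 5.22 ± 3.27 CPM in KO_PBS (-3.41 ± 0.86 and -3.23 ± 0.87, edgeR adjusted p = 0.0214 and 0.0273). These were 2 of 3 tested red blood cell genes, or 3 of 3 adjusted over the list alone, with a median of -3.23. Hba-a2 lost its call without WT 2, KO_PBS 1 or KO_PBS 2 (edgeR adjusted p = 0.0558, 0.0667 and 0.0622), and Hbb-b1 without WT 2 or any 1 of the KO_PBS libraries (up to 0.0779). Over all alternatives these ran from 3.23e-05 to 0.0822 and from 0.00277 to 0.0964. Of 9 adipocyte, 7 urothelial and 2 adrenal genes, edgeR called 0 in each list, also adjusted over the list alone, with medians of -1.16, 0.20 and -0.74. The adipocyte median was -0.02 without WT 2. Camera gave adjusted p = 0.328 for adipocyte (0.768 with an estimated correlation) and 0.956 for urothelial genes (adjusted p = 0.98 with an estimated correlation), and the urothelial sign turned under several alternatives. Of 8 male-biased kidney genes edgeR called 0, also adjusted over the list alone, with a median of -1.67 (camera adjusted p = 0.364, and adjusted p = 0.768 with an estimated correlation), and 1.31 without the male WT 2. The list passed as lower with sex as a covariate and among male libraries (camera adjusted p from 1.13e-07 to 0.768 over its alternatives). Kap, an androgen-regulated gene of the proximal tubule, was at -2.40 ± 1.0 (edgeR adjusted p = 0.114), and at -1.53 without WT 2. Of 4 female-biased genes Cyp4a14 and Slc7a12 fell (-1.98 ± 0.44 and -2.99 ± 0.89), or 3 of 4 adjusted over the list alone, with a median of -2.02. Relative to the WT mean, the mean log2 CPM of the 4 genes was 1.23 and 0.56 in the female WT 1 and WT 3. In the male WT 2 it was -1.79, within the range of the knockout libraries, all male (-2.07 to -0.98). With sex as a covariate Slc7a12 was at 0.045. Cyp4a14 lost its call without KO_PBS 1 (edgeR adjusted p = 0.0527, and 6.06e-05 to 0.351 over its alternatives). Slc7a12 lost it without any 1 of 7 libraries and was at -1.87 without WT 1 (edgeR adjusted p = 0.0539 to 0.134, and 0.00823 to 0.982 over its alternatives). Of 4 sex chromosome markers edgeR called 0, also adjusted over the list alone, with a median of 1.43. The reported miR-21 targets, 25 genes, had 4 that rose and 1 that fell, the same adjusted over the list alone, with Tpm1 at 1.81 ± 0.25, Stat3 at 1.38 ± 0.19 and Rhob at 1.40 ± 0.23. Their median was 0.03 (camera adjusted p = 0.618, and adjusted p = 0.831 with an estimated correlation). It ran from -0.17 without WT 3 to 0.18 without WT 1, and was also below 0 without KO_PBS 3.

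For the lists that passed camera in this comparison, 25 of 34, the adjusted p with an estimated correlation was the highest over each list's alternatives, and 0 of the 25 camera calls held there, while fry called 23. The gene count fell to 2423 without KO_PBS 1 and 2584 without KO_PBS 2, and with sex as a covariate or among male libraries edgeR called 0 genes (4389 at an unadjusted p under 0.05 with the covariate), both resting on 1 male WT library. Within library code L4, where 2 KO_PBS and 3 WT libraries could be set side by side, edgeR called 3116 genes, 1970 higher and 1146 lower, and 2934 of these were also called with all libraries.

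**Figure D1:**
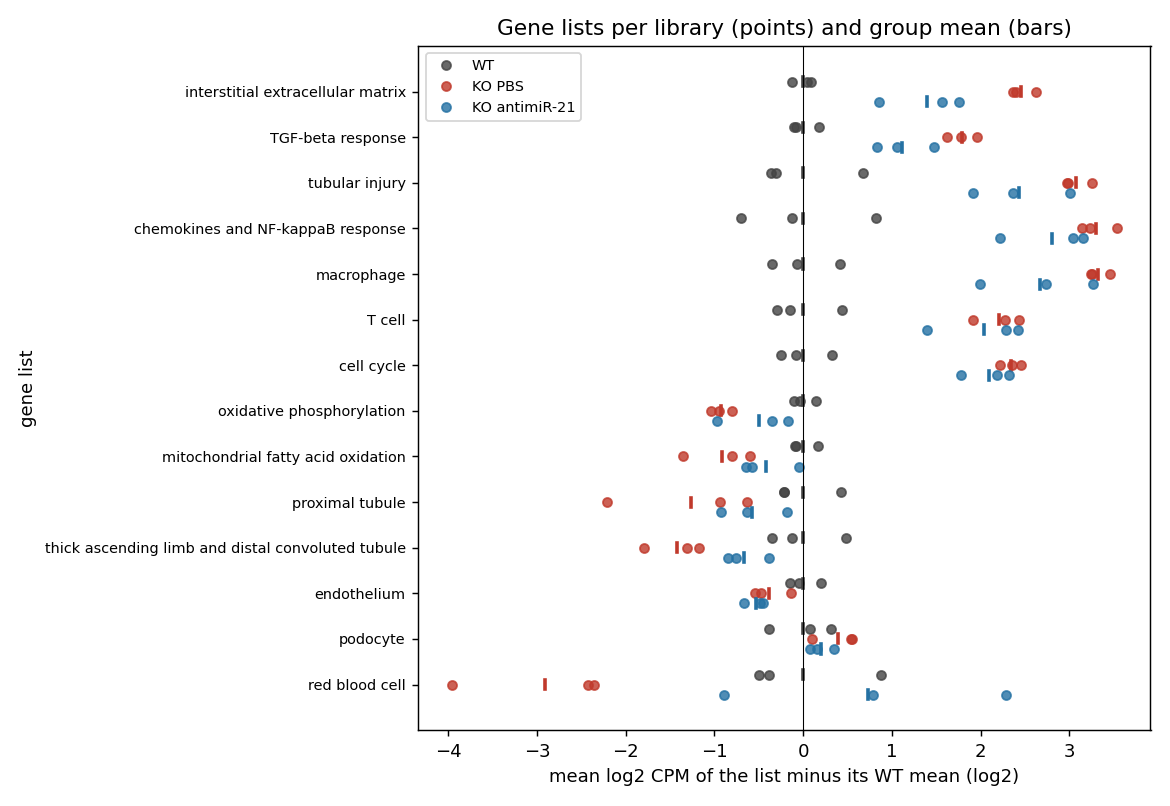
Mean log2 CPM of the genes of 14 lists in each library, minus the mean of the 3 WT libraries (x axis, log2), with points for libraries, vertical bars for group means and 1 line of the y axis per list. By group mean, matrix, injury and immune lists lie to the right of WT in both knockout groups, and tubular and metabolic lists to the left. KO_antimiR21 3 is nearest to WT among the knockout libraries for the matrix list (0.85, against 2.36 to 2.62 in KO_PBS). Its points lie among those of WT for mitochondrial fatty acid oxidation (-0.05) and proximal tubule markers (-0.18).

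The second comparison asked what the miR-21 inhibitor changed in the knockout kidney. Over all genes edgeR called 0 and DESeq2 21, and by camera with its preset correlation matrix and injury lists were lower and tubular and mitochondrial lists higher in KO_antimiR21 than in KO_PBS, among 22 of 34 lists called, where 0 were called with an estimated correlation and 0 by fry. With library code as a covariate, camera at the preset correlation called 18 lists, of which 15 were among the 22. The 18 were 8 higher and 10 lower lists, against 12 higher and 10 lower without the covariate. Col12a1 had the lowest p, at 66.8 ± 3.78 CPM in KO_PBS and 25.2 ± 6.77 CPM in KO_antimiR21 (log2 fold change -1.41 ± 0.19, unadjusted p = 4.38e-05, edgeR adjusted p = 0.707). Other matrix and contractile genes among the 10 with the lowest p were Col5a2 (-1.24 ± 0.23), Lox, a collagen cross-linking enzyme (-1.69 ± 0.36), and Tagln (-1.40 ± 0.29). Hemoglobin transcripts lay the other way, with Hba-a2 at 4.52 ± 0.90 and Hbb-b1 at 4.20 ± 0.91 (edgeR adjusted p = 0.707 for each).

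Gene by gene, edgeR called 0 of 17315 genes (1203, or 6.9%, at an unadjusted p under 0.05). Limma-voom called 0, limma on the deposited log2 matrix 0 and DESeq2 21, of which 8 were higher and 13 lower. Among the 21 were Col12a1, Col5a2, Lox, Tagln, Isyna1, Lhfp, F2r, Hba-a2, Hbb-b1, Alas2 and Pvalb (DESeq2 adjusted p = 2.12e-06 to 0.024). In the simulation of this comparison 51 of 166 DESeq2 calls were false. The 1203 became 403 without KO_antimiR21 3, 617 without KO_PBS 1, 725 without KO_PBS 2, 2558 without KO_antimiR21 2 and 221 with library code as a covariate. The groups did not overlap for 1849 genes (10.7%), where chance gives 10%. The other genes among the 10 lowest p were Isyna1, inositol phosphate synthase (-0.63 ± 0.12), Lhfp (-1.10 ± 0.22), F2r, the thrombin receptor (-1.01 ± 0.21), and Plekhb1 (0.84 ± 0.19), each at an edgeR adjusted p of 0.707. Col4a3 was at 0.66 ± 0.32 (0.42 without KO_antimiR21 3), Col4a1 at -1.03 ± 0.25 and Col4a2 at -0.94 ± 0.24, also at 0.707.

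Matrix, injury, chemokine and macrophage lists were lower by camera. Interstitial extracellular matrix had a median of -1.0 over 32 genes (camera adjusted p = 2.25e-39, and adjusted p = 0.165 with an estimated correlation), and 26 of them passed as lower adjusted over the list alone. TGF-beta response genes had a median of -0.59 (camera adjusted p = 3.9e-09, and adjusted p = 0.165 with an estimated correlation), with Ctgf at -0.91 ± 0.30. Myofibroblast and pericyte markers had a median of -0.64 (camera adjusted p = 1.25e-09, and adjusted p = 0.165 with an estimated correlation), with Acta2, smooth muscle actin, at -1.20 ± 0.29 and 2 of 11 lower adjusted over the list alone. Tubular injury genes had a median of -0.65 (camera adjusted p = 3.23e-06, and adjusted p = 0.281 with an estimated correlation), with Krt8 at -0.63 ± 0.25. The median of chemokines and the NF-kappaB response was -0.47 (camera adjusted p = 1.63e-05, and adjusted p = 0.359 with an estimated correlation), with Il1b at -1.23 ± 0.42. Macrophage markers had a median of -0.60 (camera adjusted p = 3.24e-08, and adjusted p = 0.281 with an estimated correlation), with the mannose receptor gene Mrc1 at -1.21 ± 0.33 and Cx3cr1 at -0.71 ± 0.28. Immediate early genes, listed as a check of sample quality, had a median of -0.99 (camera adjusted p = 4.2e-06, and adjusted p = 0.334 with an estimated correlation). Jun was at -0.86 ± 0.29 and Junb at -1.01 ± 0.38. Without KO_PBS 1 Il1b was at -0.64, and without KO_antimiR21 3 Cx3cr1 was at -0.39 and Krt8 at -0.42. T cell markers did not pass, with a median of -0.17 (camera adjusted p = 0.288, and adjusted p = 0.71 with an estimated correlation). Neutrophil markers (-0.29, camera adjusted p = 0.239, and adjusted p = 0.419 with an estimated correlation) and B and plasma cell markers (-0.48, camera adjusted p = 0.067, and adjusted p = 0.419 with an estimated correlation) did not pass either. The neutrophil median was 0.01 without KO_antimiR21 3 and -0.75 without KO_antimiR21 2. B and plasma cell markers passed without WT 2 (-0.48, adjusted p = 0.0416) or KO_PBS 3 (-0.60, adjusted p = 0.00136), within a range of 0.00136 to 0.42, and their median was -0.32 without KO_PBS 2 and 0.13 with library code as a covariate.

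Interferon, complement and cell cycle lists were lower by less and rested on single libraries. Their medians were -0.27 (camera adjusted p = 0.00662, and adjusted p = 0.419 with an estimated correlation), -0.33 (camera adjusted p = 0.0164, and adjusted p = 0.404 with an estimated correlation) and -0.21 (camera adjusted p = 0.000696, and adjusted p = 0.419 with an estimated correlation). Among cell cycle genes Mcm2, a replication licensing factor, was at -0.44 ± 0.14. Without KO_antimiR21 3 the medians were -0.05, -0.09 and -0.01 and none of these calls was kept (adjusted p = 0.539, 0.283 and 0.133). The interferon call was also lost without KO_PBS 1 (-0.11, adjusted p = 0.118), and with library code as a covariate its median was 0.01. Without KO_antimiR21 2 the medians were -0.44, -0.51 and -0.36, and the cell cycle median was -0.13 without KO_PBS 2. Over all alternatives the adjusted p ran from 0.000107 to 0.99 for interferon, 0.00503 to 0.404 for complement and 7.06e-05 to 0.419 for cell cycle genes.

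Metabolic and tubular lists were higher by camera. Medians were 0.48 for mitochondrial fatty acid oxidation (camera adjusted p = 5.99e-11, and adjusted p = 0.281 with an estimated correlation), with Etfb at 0.82 ± 0.27, and 0.53 for peroxisomal lipid metabolism (camera adjusted p = 4.05e-08, and adjusted p = 0.281 with an estimated correlation). PPAR-alpha targets had a median of 0.48 (camera adjusted p = 0.000173, and adjusted p = 0.281 with an estimated correlation). Their adjusted p ran from 7.5e-07 to 0.65 over all alternatives. Oxidative phosphorylation genes had a median of 0.48 (camera adjusted p = 4.2e-26, and adjusted p = 0.281 with an estimated correlation), with Ndufa4 at 0.76 ± 0.27, and TCA cycle genes one of 0.44 (camera adjusted p = 1.31e-09, and adjusted p = 0.334 with an estimated correlation), with Fh1 at 0.57 ± 0.20. Branched-chain amino acid genes had a median of 0.61 (camera adjusted p = 4.62e-10, and adjusted p = 0.281 with an estimated correlation), with Mccc2 at 0.70 ± 0.27. Proximal tubule markers had a median of 0.59 (camera adjusted p = 2.45e-08, and adjusted p = 0.334 with an estimated correlation), with Aqp1 at 0.73 ± 0.33 and Pck1 at 1.12 ± 0.52. For that list the adjusted p ran from 1.52e-12 to 0.528 over all alternatives. Markers of the thick ascending limb and distal convoluted tubule had a median of 0.55 (camera adjusted p = 3.18e-07, and adjusted p = 0.165 with an estimated correlation), with Slc12a1 at 0.86 ± 0.31 and Pvalb at 2.48 ± 0.60, and 1 of 12 was higher adjusted over the list alone. Collecting duct markers had a median of 0.26 (camera adjusted p = 0.000237, and adjusted p = 0.218 with an estimated correlation). Without KO_antimiR21 3 Aqp1 was at 0.44, Pck1 at 0.69 and Mccc2 at 0.46, and without KO_antimiR21 1 Ndufa4 was at 0.45 and Etfb at 0.55.

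Red blood cell genes lay higher in the same libraries, with a median of 4.20 over 3 genes, including Alas2 at 3.62 ± 0.84, and all 3 passed adjusted over the list alone. Antioxidant and NRF2 genes had a median of 0.26 (camera adjusted p = 0.0159, and adjusted p = 0.359 with an estimated correlation), with Sod1 at 0.72 ± 0.27. This call was lost without KO_PBS 1 (0.15, adjusted p = 0.127) or KO_antimiR21 3 (adjusted p = 0.0663), within a range of 0.000983 to 0.359. Male-biased kidney genes had a median of 1.12 (camera adjusted p = 0.00916, and adjusted p = 0.419 with an estimated correlation), with Kap at 1.59 ± 0.97. Their call was lost without KO_PBS 1 (0.68, adjusted p = 0.183) or KO_antimiR21 3 (0.49, adjusted p = 0.133), within a range of 6.29e-05 to 0.452. Adipocyte markers had a median of 2.20 (camera adjusted p = 0.0367, and adjusted p = 0.501 with an estimated correlation), with Car3 at 2.20 ± 1.06. They rested on KO_antimiR21 3: without it their median was -1.49 (adjusted p = 0.0143) and Car3 stood at -0.08. The adipocyte call was also lost without WT 3 (adjusted p = 0.05) or KO_PBS 3 (adjusted p = 0.52), within a range of 3.02e-06 to 0.602. The reported miR-21 targets did not pass, with a median of -0.04 (camera adjusted p = 0.0537, and adjusted p = 0.436 with an estimated correlation). Tpm1 was at -0.90 ± 0.24, Spry1 at -0.72 ± 0.29 (-0.48 without KO_antimiR21 3) and Rhob at -0.55 ± 0.23. That list passed as lower without WT 1, KO_PBS 1, KO_antimiR21 2 or KO_antimiR21 3 (adjusted p = 0.043, 0.0152, 0.0164 and 0.0108), and its median turned to 0.04 without KO_antimiR21 1 (adjusted p = 0.837), within a range of 0.0108 to 0.837. T cell markers passed without KO_PBS 1 (-0.32, adjusted p = 0.0388) and turned to 0.08 without KO_antimiR21 3 (adjusted p = 0.229) and 0.03 without KO_PBS 2 (adjusted p = 0.786), within a range of 0.0388 to 0.786.

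Single libraries also moved the medians of lists that kept their camera calls. Without KO_antimiR21 3 the medians were -0.37 for tubular injury, -0.20 for chemokines, -0.30 for macrophage, 0.32 for fatty acid oxidation, 0.32 for peroxisomal lipid, 0.31 for PPAR-alpha target, 0.25 for TCA cycle, 0.29 for branched-chain amino acid and 0.39 for proximal tubule genes. Without KO_PBS 1 they were -0.40 for tubular injury, 0.32 for peroxisomal lipid, 0.20 for PPAR-alpha target and 0.30 for proximal tubule genes. Without KO_PBS 3 they were 0.80 for peroxisomal lipid, 0.89 for PPAR-alpha target and 0.99 for proximal tubule genes. Oxidative phosphorylation genes stood at 0.32 without KO_antimiR21 1, collecting duct markers at 0.40 and macrophage markers at -0.92 without KO_antimiR21 2.

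Each single library's mean over the matrix list was 2.40, 2.62 and 2.36 above the WT mean in KO_PBS and 1.57, 1.76 and 0.85 in KO_antimiR21, on the log2 scale. That difference of -1.07 had an exact permutation p of 0.1 (two-sided), the smallest that 3 against 3 libraries allow. The same test gave 0.1 for the TGF-beta response, myofibroblast, immediate early, thick ascending limb, collecting duct and red blood cell lists. It gave 0.2 for chemokine and fatty acid oxidation lists, and 0.3 for tubular injury, macrophage, oxidative phosphorylation, TCA cycle and proximal tubule lists. For interferon genes it gave 0.5. In macrophage markers KO_antimiR21 2 stood at 3.27, within the 3.25 to 3.46 of KO_PBS. That library was also within the KO_PBS range for chemokine (3.15), tubular injury (3.01) and fatty acid oxidation genes (-0.64). The same held for oxidative phosphorylation (-0.97), TCA cycle (-0.77) and proximal tubule genes (-0.93). In each list with a permutation p of 0.1 it was outside that range. Within library code L5, where 1 KO_PBS library stood against 3 KO_antimiR21 libraries, edgeR called 0 genes (175 at an unadjusted p under 0.05).

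**Figure D2:**
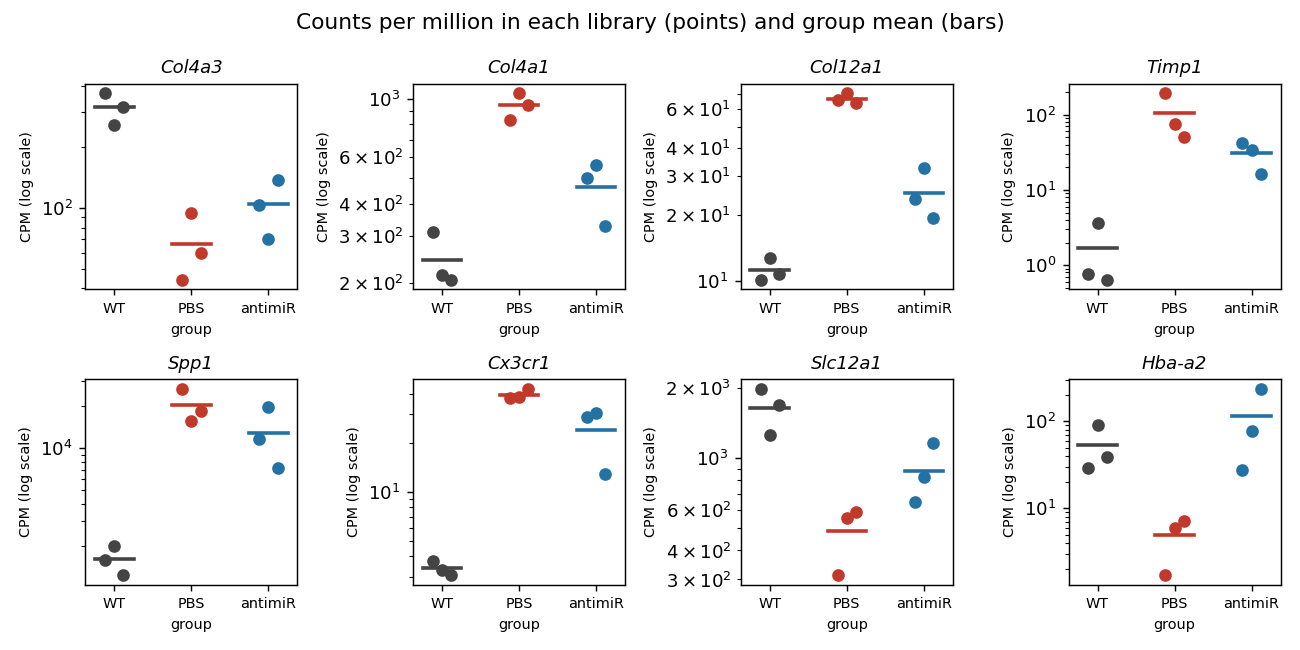
CPM on a log scale (y axis) of 8 genes in each library (points) with the group mean (bars), for WT, KO_PBS and KO_antimiR21 (x axis). Col4a1, Col12a1, Timp1, Spp1 and Cx3cr1 are higher in both knockout groups than in WT, Col4a3 and Slc12a1 are lower, and Hba-a2 is lowest in KO_PBS.

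If the inhibitor releases targets of miR-21, genes whose 3' untranslated region holds a seed site would be higher as a set in KO_antimiR21 than in KO_PBS. The mean log2 fold change of the 1101 genes with a 7-mer-m8 site lay 0.0215 above that of the genes without, and that of the 333 genes with an 8-mer site 0.0644 above. By camera, p was 0.435 and 0.202. In a test added after the data were seen, library mean log2 CPM adjusted for length and GC content of the region differed by 0.0543 and 0.0743, with p of 0.3 and 0.2 by exact permutation of the 6 libraries (two-sided, 0.1 being the smallest possible). None of the 100 control sites reached the differences of fold changes (7-mer controls -0.0407 to 0.0115, 8-mer controls -0.0617 to 0.0455). In KO_PBS against WT the 7-mer-m8 genes lay lower by a difference of -0.134, with 100 of the 100 controls at or above.

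The 7-mer-m8 difference moved with single libraries, and the control sites moved with it. It was -0.0342 without KO_PBS 1 (controls -0.0882 to -0.0376, 0 of 100 at or above), -0.0272 without KO_antimiR21 2 (-0.123 to -0.0335, 0 of 100) and -0.0136 without KO_antimiR21 3 (-0.0663 to -0.00972, 1 of 100). Without KO_PBS 3 it was 0.0673 (-0.00704 to 0.0564, 0 of 100), and without KO_antimiR21 1 it was 0.0874 (0.0256 to 0.0897, 1 of 100), the only one of these that passed camera at 0.05. Adjusted in the same way, it was 0.0544 with all libraries and 0.0355, 0.0566 and 0.0402 without KO_PBS 1, KO_antimiR21 2 and KO_antimiR21 3, with 0 of 100 controls at or above in each. With library code as a covariate it was -0.0718 (controls -0.118 to -0.0558, 22 of 100 at or above), and 0.0155 when adjusted (17 of 100). With the log2 fold change of KO_PBS against WT adjusted for as well, it was 0.0219 (controls -0.0189 to 0.0261, 1 of 100 at or above). The covariate and the adjustments were added after the data were seen.

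The 8-mer difference moved too. It was 0.0217 without KO_PBS 1, 0.0235 without KO_antimiR21 2, 0.0351 without KO_antimiR21 3, 0.127 without KO_PBS 3 and 0.14 without KO_antimiR21 1, with 0 of 100 controls at or above in each. With library code as a covariate it was -0.0376 (controls -0.159 to -0.0154, 5 of 100 at or above). Adjusted for length, GC content and the log2 fold change of KO_PBS against WT, it was 0.0504 (controls -0.0269 to 0.0477, 0 of 100).

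The third comparison asked how far inhibitor-treated knockout kidneys stood from wild type. By camera, chemokine, matrix and cell cycle lists were higher than in WT, among 22 of 34 lists called, where 0 were called with an estimated correlation and 13 by fry. Il1rn rose by 4.79 ± 0.67 (edgeR adjusted p = 0.00477), the chemokine Ccl5 by 4.40 ± 0.79 (edgeR adjusted p = 0.0109), Ccl2 by 4.04 ± 0.75 (edgeR adjusted p = 0.013), and complement component C3 went from 115 ± 91.1 to 1913 ± 1136 CPM (4.05 ± 0.65, edgeR adjusted p = 0.00729). Vcam1, an adhesion molecule of activated endothelium, rose by 4.05 ± 0.61 (edgeR adjusted p = 0.00574) and Ubd by 4.65 ± 0.88 (edgeR adjusted p = 0.0141).

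EdgeR called 1238 genes, 1164 higher and 74 lower in KO_antimiR21 than in WT. The 74 lower genes became 33, 16, 17 and 2 without WT 1, WT 3, KO_antimiR21 1 and KO_antimiR21 2, 23 and 24 without KO_PBS 2 and KO_PBS 3, and 158 and 135 without WT 2 and KO_antimiR21 3. The groups did not overlap for 4236 genes (24.5%), where chance gives 10%. Krt20 (4.53 ± 0.98, edgeR adjusted p = 0.0255) and Timp1 (4.20 ± 0.79, edgeR adjusted p = 0.0133) were among the 8 named rises. Krt20 lost its call without WT 1, WT 3, KO_antimiR21 1 or KO_antimiR21 2 (edgeR adjusted p = 0.0572 to 0.0882, and 0.00102 to 0.423 over its alternatives), and was at 7.36 without WT 2. Timp1 lost it without WT 1 or WT 3 (edgeR adjusted p = 0.0532 and 0.0565, and 3.62e-08 to 0.258 over its alternatives).

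The 8 named genes that fell were Corin (-2.21 ± 0.55), Slc9a8, a sodium-proton exchanger (-1.79 ± 0.34), D3Bwg0562e (-1.74 ± 0.44), Acsm1 (-1.66 ± 0.39), Slc6a17 (-1.61 ± 0.39), Col4a3, Ank2 (-1.55 ± 0.31) and Ccbl2 (-1.40 ± 0.33), with edgeR adjusted p from 0.0148 to 0.0467. Each lost its call without KO_antimiR21 1 and without KO_antimiR21 2. All but Slc9a8 lost it without WT 1 and without WT 3 too. Corin and D3Bwg0562e lost it without KO_PBS 2 or KO_PBS 3, Ccbl2 without KO_PBS 3, and Acsm1 and Slc6a17 without any 1 of the KO_PBS libraries. Without KO_antimiR21 3 Acsm1 and D3Bwg0562e lost it as well. The highest edgeR adjusted p with 1 library left out ran from 0.056 (Slc9a8) to 0.176 (Corin), and over all alternatives from 1.18e-05 to 0.56.

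Of 32 matrix genes 19 rose (25 adjusted over the list alone), with Mmp2 at 1.93 ± 0.23 and Mgp, matrix Gla protein, at 2.79 ± 0.38, and a median of 1.33 (camera adjusted p = 1.17e-21, and adjusted p = 0.134 with an estimated correlation). Of 18 tubular injury genes 10 rose (16 adjusted over the list alone), with Spp1 at 2.99 ± 0.43 and Cd44 at 3.97 ± 0.59, and a median of 2.01 (camera adjusted p = 1.07e-17, and adjusted p = 0.123 with an estimated correlation). Of 20 chemokine and NF-kappaB genes 16 rose (19 adjusted over the list alone), with Icam1 at 2.24 ± 0.27 and Ccl7 at 4.28 ± 0.61, and a median of 3.13 (camera adjusted p = 4.19e-26, and adjusted p = 0.104 with an estimated correlation). Of 12 complement genes 9 rose (11 adjusted over the list alone), with a median of 1.72 (camera adjusted p = 1.87e-17, and adjusted p = 0.0753 with an estimated correlation). Of 23 cell cycle genes 21 rose (23 adjusted over the list alone), with Cdc2a at 3.11 ± 0.30 and a median of 2.36 (camera adjusted p = 1.73e-47, and adjusted p = 0.0753 with an estimated correlation). Of 16 macrophage markers 15 rose, also 15 adjusted over the list alone, with Cx3cr1 at 2.84 ± 0.31 and C1qb at 2.97 ± 0.36, and a median of 2.96 (camera adjusted p = 2.69e-34, and adjusted p = 0.0922 with an estimated correlation). Of 14 T cell markers 10 rose (14 adjusted over the list alone), with Cd3g at 2.67 ± 0.47 and a median of 2.13 (camera adjusted p = 2.03e-12, and adjusted p = 0.145 with an estimated correlation).

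Some metabolic lists were lower by camera, with few single genes past the threshold. Of 17 branched-chain amino acid genes 1 fell, Mccc2 at -1.08 ± 0.27 (4 adjusted over the list alone), with a median of -0.64 (camera adjusted p = 1.98e-06, and adjusted p = 0.364 with an estimated correlation). Mccc2 (edgeR adjusted p = 0.0479) lost its call without any 1 of the 3 WT libraries, KO_PBS 2, KO_PBS 3, KO_antimiR21 1 or KO_antimiR21 2 (up to 0.165, and 0.00406 to 0.494 over its alternatives). In the lists of oxidative phosphorylation, fatty acid oxidation and proximal tubule markers edgeR called 0 genes, also adjusted over the list alone. Their medians were -0.46 (camera adjusted p = 3.57e-13, and adjusted p = 0.422 with an estimated correlation), -0.38 (camera adjusted p = 0.00134, and adjusted p = 0.527 with an estimated correlation) and -0.61 (camera adjusted p = 0.00108, and adjusted p = 0.527 with an estimated correlation). Without KO_antimiR21 2 the first 2 medians were -0.23 and -0.24, and without WT 1 fatty acid oxidation was at -0.21 and the proximal tubule list at -0.40, with its call lost (adjusted p = 0.0503, range 2.72e-10 to 0.527). Miox was at -1.70 ± 0.58 (edgeR adjusted p = 0.133).

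The lists of PPAR-alpha targets and antioxidant genes did not pass. Of 22 PPAR-alpha targets 2 rose, also 2 adjusted over the list alone, with a median of -0.08 (camera adjusted p = 0.886, and adjusted p = 0.997 with an estimated correlation). That median was 0.08 without WT 1, 0.13 without KO_antimiR21 1 and -0.40 without KO_antimiR21 3, and the list passed as lower with library code as a covariate, within a range of 0.0215 to 0.997. Of 17 antioxidant and NRF2 genes 1 rose, also 1 adjusted over the list alone, with a median of -0.23 (camera adjusted p = 0.14, and adjusted p = 0.527 with an estimated correlation). That list passed as lower without WT 3 (-0.18, adjusted p = 0.0403), within a range of 0.0161 to 0.527, and its median was -0.04 without KO_antimiR21 2.

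Without WT 1, WT 3, KO_antimiR21 1 or KO_antimiR21 2 the gene count was 758, 667, 795 and 679, and every WT library had library code L4 and every KO_antimiR21 library L5. With that code, or sex, as a covariate edgeR called 0 genes.

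Both knockout groups were set side by side against WT. Of the called genes, 1161 were higher in both comparisons, where independent lists would share 169.5, and 70 were lower in both, where independent lists would share 7.3. In simulations of unchanged groups with the same WT libraries, the 4226 and 1238 genes of lowest p, taken without regard to threshold or direction, shared 347.6 higher and 285.4 lower genes on average. Numbers of higher and lower genes in those lists were not matched to the observed ones, so the simulated counts are not directly comparable by direction. Without WT 1, WT 3, KO_antimiR21 1 or KO_antimiR21 2 the total of 1231 was 755, 665, 791 and 678, counted without regard to direction. Across genes the log2 fold changes had a correlation of 0.905 (0.503 simulated) and a covariance of 0.861 (0.0837 simulated), a difference of 0.778; genes are not independent replicates. Part of the excess in shared calls over independent lists may come from the shared WT libraries, since 3 libraries do not give 2 on each side of a split.

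Of the 4226 genes called in KO_PBS against WT, 96% had the opposite sign in KO_antimiR21 against KO_PBS, where unchanged groups that share the KO_PBS libraries gave 81.2% (79.7% to 82.3%) over the 4226 genes of lowest p in 20 simulations. The correlation across genes was -0.673 (-0.501 simulated, -0.548 to -0.466) and the covariance -0.368 (-0.0832 simulated), a difference of -0.285. Each gene was drawn independently in these simulations, and genes that vary together would widen the simulated ranges. The simulated groups held no disease difference either, so their genes of lowest p were picked on random variation alone. The 81.2% is therefore not the share for a real disease difference with an inert inhibitor, which was not simulated. The share with opposite sign was 86% without KO_antimiR21 3. With disease fitted from L4 and treatment from L5, no library entered both fits. The share was then 89.6% by edgeR, with a correlation of -0.265 across genes. The L5 side held 1 KO_PBS library, KO_PBS 3. That library also helped to choose the 4226 genes, so the 89.6% was not free of shared libraries.

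**Figure D3:**
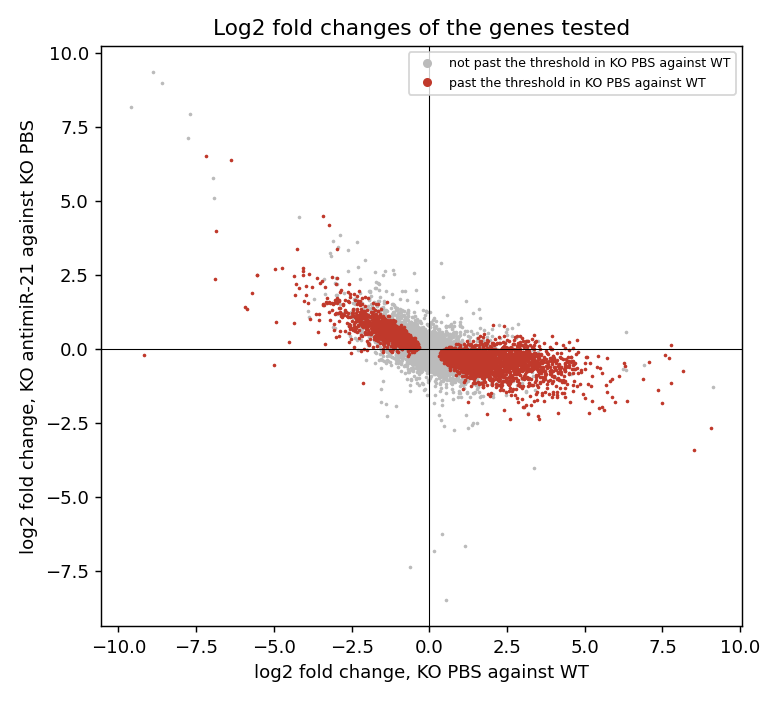
Log2 fold change of KO_PBS against WT (x axis) and of KO_antimiR21 against KO_PBS (y axis) for the 17315 genes tested, with 1 point per gene. Of the 4226 genes past the threshold on the x axis (coloured points), 96% have the opposite sign on the y axis. Simulations of unchanged groups that share libraries, with genes drawn independently, gave 81.2%. These held no disease difference, so 81.2% is not the share for a real disease difference with an inert inhibitor.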

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

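The fit on male libraries only was chosen after the data were seen, and the other alternatives here were planned. Every alternative gave a value. The genes and lists named in the text were a part chosen after these values were seen, which left out some uncalled items that changed sign. The rule covers 478 genes and lists, each counted once per comparison in which it is taken. Over their 8420 pairings with an alternative, 7405 kept direction and side of the threshold, 733 lost a call and 144 gained one. The other 138 changed sign in 63 items, 131 of these where neither value passed. The text gives 224 of the 478, with 20 of the sign changes.

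In KO_PBS against WT, the 4226 genes became 1648 at an adjusted p under 0.01 and 2814 with a log2 fold change of at least 1, both by construction. They became 0 with sex as a covariate and 0 among male libraries only, where 1 male WT library was left to compare, and ran from 2423 to 4332 with 1 library left out. In KO_antimiR21 against KO_PBS, DESeq2 gave 21 genes against 0 by edgeR. In KO_antimiR21 against WT, the 1238 genes became 2002 with DESeq2, 707 with only the groups compared in the fit, 497 at an adjusted p under 0.01, and 0 with sex as a covariate, 0 with library code as a covariate and 0 among male libraries only, and 667 to 1602 with 1 library left out. The cause of the DESeq2 counts was not tested. Library code was the same within every WT and every KO_antimiR21 library, so that covariate left only KO_PBS to estimate it.

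The lists called by camera (25, 22 and 22 in the 3 comparisons) became 0, 0 and 0 with an estimated correlation. By fry, which asks another question, 0 were called in KO_antimiR21 against KO_PBS and 13 in KO_antimiR21 against WT. Col4a3 was at -1.96 with sex as a covariate and -1.93 among male libraries in KO_PBS, no longer past the threshold. The share of opposite signs was 86% to 96.9% with 1 library left out. The 1231 genes called in both knockout groups, all in the same direction, became 1957 with DESeq2 and 665 to 1583 with 1 library left out. They became 0 with sex and 0 with library code as a covariate. Direction was not checked in these alternatives. The difference for miR-21 seed sites ran from -0.0342 to 0.0874 with 1 library left out, where the control sites moved as well (-0.0882 to -0.0376 and 0.0256 to 0.0897).

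Genes and lists are counted here once per comparison in which they are given. Over the 152 genes and their alternatives, 2217 pairings kept direction and side of the threshold, 351 lost a call and 13 gained one. Over the 73 lists the numbers were 1273, 137 and 33. Of the genes, 110 lost a call with sex as a covariate and 31 with library code, and of the lists 58 lost one with an estimated correlation. Changes of direction, of which the cause was not tested, were as follows. In KO_PBS against WT the urothelium list (0.20) was at -0.71 with sex as a covariate, -0.68 among male libraries and -0.39 to 0.85 with 1 library left out, and its camera direction turned while its median was 0.27 with upper quartile scaling and 0.485 with library size only. The male-biased list ran from -2.26 to 1.31 with 1 library left out, and Slc7a12 was at 0.045 with sex as a covariate and 0.067 among male libraries. In KO_antimiR21 against KO_PBS the interferon list was at 0.014 and the B and plasma cell list at 0.132 with library code as a covariate. With 1 library left out, T cell markers ran from -0.32 to 0.076, adipocyte markers from -1.49 to 2.73 and Car3 from -0.075 to 2.73. In KO_antimiR21 against WT the PPAR-alpha list (-0.079) was at 0.132 with sex as a covariate, 0.164 among male libraries and -0.398 to 0.13 with 1 library left out, and fry gave it the upward direction.

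With the replicate number as a block, edgeR called 3205, 0 and 923 genes and camera 24, 24 and 23 lists in the 3 comparisons. Under the block Col4a3 was at -2.25 and the share of opposite signs was 96.4%. There 922 genes were called in both knockout groups, direction unchecked, and the seed difference was 0.0215. Of the genes given, 6 lost a call under the block. Deviations from the group means correlated from -0.367 to 0.438 in 9 pairs of libraries with the same number, 3 of them above 0.1, and from -0.357 to 0.44 in 18 other pairs, 7 above 0.1, so the numbers did not pair the samples. At this depth and with 3 libraries per group, edgeR recovered 11.5% of simulated 2-fold changes in KO_antimiR21 against KO_PBS, so changes of that size were mostly below detection there.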

Other observations

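The splits of the samples and the test of sex were planned, and the other tests and the genes named here were chosen after their values were seen.

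Cyp27b1, which encodes the enzyme that makes active vitamin D, was higher in KO_PBS than in WT (log2 fold change 2.70 ± 0.49, edgeR adjusted p = 0.00574). It stood at 5.57, 16.2 and 29.2 CPM in WT 1, 2 and 3, at 124, 106.8 and 100.3 CPM in KO_PBS and at 56.7, 67.5 and 43.0 CPM in KO_antimiR21. With 1 library left out its edgeR adjusted p ran from 0.00717 to 0.0209, and over all alternatives from 1.39e-07 to 0.0935, with the call lost when sex was a covariate. In KO_antimiR21 against KO_PBS it was at -0.98 ± 0.46 (edgeR adjusted p = 0.707).

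Dbp, a clock output gene, and Arntl, which encodes the clock activator BMAL1, differed between libraries of 1 group. Dbp stood at 81.0, 123.8 and 196.7 CPM in WT, at 41.4, 20.7 and 80.0 CPM in KO_PBS and at 177.6, 65.6 and 144.2 CPM in KO_antimiR21. Arntl stood at 9.49, 5.53 and 3.26 CPM in WT, at 6.33, 11.2 and 3.11 CPM in KO_PBS and at 1.28, 4.87 and 2.50 CPM in KO_antimiR21. Within each group the library with the highest Arntl had the lowest Dbp. Times of collection were not given in the sources used here. Adipoq, a fat cell gene, stood at 28.3 CPM in KO_antimiR21 3 and at 9.38 CPM or less in every other library. Fos stood at 1.01 CPM in WT 1 against 18.3 and 13.3 CPM in WT 2 and WT 3.

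For the difference between KO_PBS and WT, splitting the 6 libraries in each of the 10 possible ways gave 4226 genes for the real split and 0 for the highest of the others, so 1 of 10 was as large. Splits were too few for a share under 0.05, as they were for KO_antimiR21 against WT (real 1238, highest other 0, 1 of 10). For KO_antimiR21 against KO_PBS the count was 0 in 10 of 10 splits, which decides nothing. At an unadjusted p under 0.05 the real split there gave 1203 genes and the highest of the others 1775, with 5 of 10 as large. Sex as the whole cause was argued against, since with sex as a covariate the median ratio of adjusted to unadjusted log2 fold change over the called genes was 0.935 (spread 0.28), with the median SE going from 0.29 to 0.41 and 0 edgeR calls (4389 at an unadjusted p under 0.05). That ratio covers called genes, which were picked partly for a small spread within WT, so a ratio near 1 was favoured. Over all tested genes, on an axis from the WT mean (0) to the knockout mean (1), the male WT 2 stood at 0.138. WT 1 and WT 3 stood at -0.101 and -0.037, and the knockout libraries at 0.603 to 1.272. Ratio and axis rest on 1 male WT library, so sex may still contribute in part. A lower share of proximal tubule cells as the whole cause was argued against, since the macrophage median exceeded the endothelium median by 3.88 (spread 0.40), and the knockout together with its injection stays open as a candidate explanation.

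The opposite direction of the disease and the inhibitor comparisons was weighed next. Shared KO_PBS libraries alone stay open. The covariance across genes was -0.3684, where 20 simulations gave -0.0956 to -0.0756, but these drew each gene independently. In the real libraries genes varied together (estimated correlation 0.733 in the oxidative phosphorylation list), so that range was too narrow to decide. Severity that varied among knockout animals regardless of the injection stays open, since the position of the 6 knockout libraries, on an axis from the WT mean to the mean of all 6, gave an exact permutation p of 0.1, the smallest that 3 against 3 allow. Library code stays open too. With no library or code shared between the 2 sides, 91.1% of the called genes had opposite signs (spread 14.6). With the code as a covariate 89.5% had. Code L5 held 1 KO_PBS library and both values rest on it. That library also helped to choose the called genes, so neither share was free of shared libraries. An effect of the inhibitor may account for the pattern and cannot be told apart from these.

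Red blood cell transcripts, which were lower in KO_PBS than in WT, were weighed last. Library code as the whole cause was argued against, since within code L4 the mean log2 difference of Hba-a2 and Hbb-b1 was -3.82. Less blood left in the KO_PBS kidneys may account for it and stays open, since neutrophil markers had a median of 1.71, which infiltrating cells could also bring. No biological explanation of these lower transcripts was tested.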
